A study of Mus musculus with 61 samples.

How the data were processed

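RNA was measured by sequencing in 61 libraries of male mice aged 6 to 8 weeks on a C57BL/6J background, either WT or homozygous for the G542X nonsense allele of Cftr (CF), per the labels' protocols. Total RNA, depleted of ribosomal RNA and with strand information kept in the library, was read in pairs of 75 bases for the duodenum, jejunum and jejunal crypts and of 100 bases, on another instrument, for the ileum. Reads were trimmed with Trimmomatic 0.39 and aligned to mm10 with Bowtie2 and TopHat2 2.1.1, and expression was estimated with Cufflinks and Cuffdiff 2.1.1, per the submitters' processing notes. The deposited values are FPKM, fragments scaled to transcript length and library size, computed by the authors for each assembled locus and library. The library scaling behind these FPKM values, the annotation and the strand setting of the counting are not stated in the labels.

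The 3 tables hold 24540 loci for the duodenum, 24592 for the jejunum with its crypts and 24486 for the ileum. All columns were matched to samples by name, and 0 columns were unmatched. Because the labels do not state whether the 3 tables share a scaling, genotypes were tested within a table only, and genotype effects in different segments were compared through their calls and direction. The only exceptions are the position of a library between the WT means of 2 segments and the Cftr value of 1 WT duodenum library. They set FPKM levels of different tables side by side, and there a difference between tables or instruments is not separated from one between segments. FPKM values hold no read counts, so the sequencing depth of each library is unknown and no interval or detection floor that needs it is given. A symbol that stood on more than 1 locus was represented by the locus with the higher mean FPKM. A value of an assembled locus may include reads of a neighbouring or overlapping gene or of a close paralog. Among 102 named genes, 26 shared their locus with another coding gene of GENCODE release M21. Libraries were checked for mixed-up sex: all 61 had Ddx3y above 5 FPKM and Xist below 1 FPKM, and 0 pairs of libraries were identical.

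Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with empirical Bayes moderation and a trend of the variance with the mean, over the genes with a mean of at least 1 FPKM in the libraries of the fit. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adding 1 to the FPKM makes the fold changes of weakly expressed genes smaller than their ratios of FPKM. Genes were counted as changed at least 2-fold when the log2 change reached 1 in either direction. CF was compared with WT in the duodenum, whole jejunum, ileum and jejunal crypts. A joint fit of the jejunum and crypt libraries gave the difference between crypts and whole tissue in WT and the difference between the genotype effects in crypts and whole tissue. The labels do not state whether the segments of 1 animal share a replicate number, and the p-values treat each labelled sample as an independent animal.

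A total of 51 gene lists for metabolism, transport, cell types and stress responses was tested, those with at least 5 measured members per comparison, which left at most 47. The limma function camera compared each list with all other genes at a preset correlation of 0.01 between genes, and once more with the correlation estimated from the data. Counts of members past the threshold come from the tests of single genes, over all genes tested and adjusted over the list alone.

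Genes named in the text follow a rule. In each comparison of CF with WT, Cftr, Slc2a2 and Slc5a1 were always taken, then the 6 largest positive and 6 largest negative log2 changes past the threshold among genes with a standard symbol. Up to 4 members of the glycolysis list and of the list of glucose and fructose transporters with the smallest adjusted p were added, and the 2 members with the smallest adjusted p of up to 10 called lists with the smallest p. For crypts against whole jejunum the 5 largest changes in each direction were taken, for the difference of genotype effects the 5 smallest adjusted p in each direction, and for all 3 segments the 10 genes with the largest smallest change. Other list members appear as values. Single-gene results of some genes that the rule takes are not reported here, and these genes stay in all counts. The comparisons, the tests, the gene lists, this rule and most alternatives were fixed before the data were examined.

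Alternatives were a pseudocount of 0.1, no filter on low values, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, limma's array weights, the replicate number as a block, a Wilcoxon rank-sum test and leaving out each library in turn. Added after seeing the data were a run without libraries whose median-of-ratios factor was under 0.8, the run without 1 WT duodenum library, and the list counts under the 2 scalings. The libraries of each comparison were also split at random into groups of the same sizes, with 100 splits including the real one.

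The fit was tested on simulated data with the sizes and spreads of each comparison, 200 of the genes changed, 100 by 0.5 and 100 by 1 on the log2 scale. In the duodenum 62% of the smaller and 97% of the larger changes were recovered, in the jejunum 81% and 99%, in the ileum 58% and 92%, and in the crypts 62% and 94%. False calls made up 4.22%, 2.7%, 2.6% and 3.7% of the calls, in the same order. The simulated genes varied independently of each other, so this test says nothing about lists of genes that vary together. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.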

Results

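Expression was measured in 8 groups of samples from CF and WT mice that ate a diet with 45% of its energy as fat and drank acidified water. The small intestine was flushed and segments of 3 inches were taken from its beginning, middle and end. The duodenum gave 9 CF and 9 WT libraries, the whole jejunum 9 and 8, crypts isolated from the other part of the jejunum section 9 and 8, and the ileum 5 and 4. Values above 0 were listed for 15935 to 19766 loci per library, with the lowest number in crypts. The 10 most abundant loci held from 10.1% to 58.6% of a library's summed FPKM, and this share varied most in the duodenum. The study concerns glucose uptake and glycolysis in the CF intestine, and each comparison therefore gives the glucose genes beside the largest changes.

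Cftr (mm10 chromosome 6, 18170605 to 18322935 in the duodenum table, XLOC_021308), the chloride and bicarbonate channel gene that carries the nonsense allele, was lower in CF tissue in every comparison. In the duodenum its mean was 10.6 ± 2.26 FPKM in CF (SD, n = 9) and 30.5 ± 11 in WT (n = 9), a log2 change of -1.37 (SE 0.2, adjusted p = 6.86e-05). In the jejunum (XLOC_023146) it was 9.66 ± 2.26 in CF (n = 9) and 29.1 ± 3.09 in WT (n = 8), a change of -1.52 (SE 0.116, adjusted p = 7.05e-09). Ileum libraries (XLOC_020669) had 7.97 ± 1.58 in CF (n = 5) and 23.9 ± 4.21 in WT (n = 4; adjusted p = 4.3e-05). Crypts had 9.19 ± 3.13 in CF (n = 9) and 34.9 ± 2.63 in WT (n = 8), a change of -1.87 (SE 0.145, adjusted p = 4.77e-08). CF and WT libraries did not overlap in the jejunum, ileum or crypts. In the duodenum WT library 7 had 12 FPKM, within the CF range of 7.65 to 14.3. A second, weaker Cftr locus of the duodenum table (XLOC_021309) was at 2.7 ± 1.03 FPKM in CF and 2.9 ± 1 in WT.

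**Figure D1:**
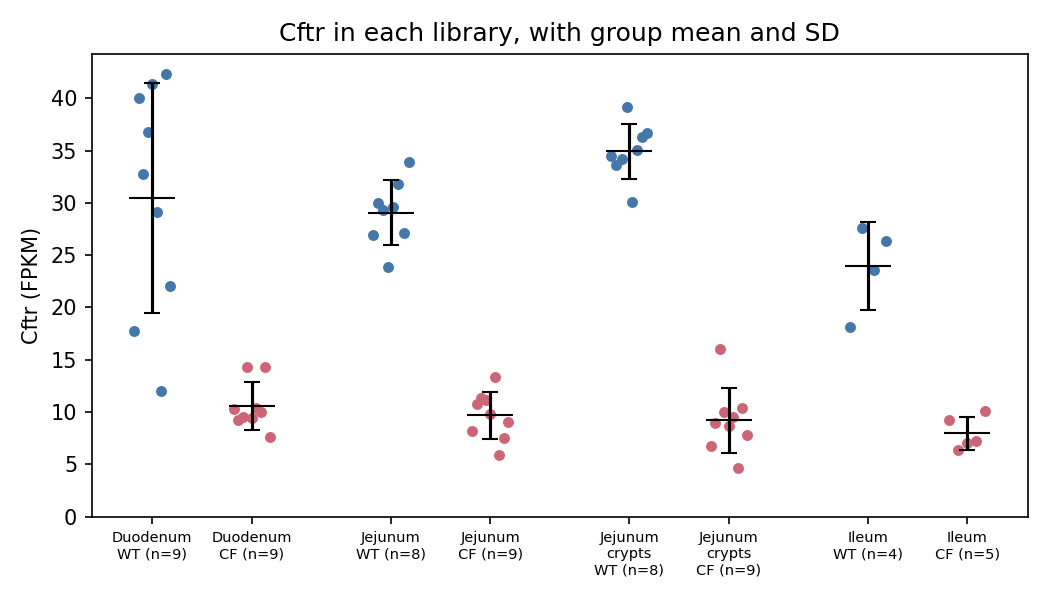
Cftr FPKM (vertical axis) per library for CF and WT in the duodenum, jejunum, ileum and jejunal crypts, with points for libraries and bars for the group mean and SD. CF libraries lie between 4.67 and 16.1 FPKM, and WT libraries between 12 and 42.4.

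In the duodenum of CF mice, Reg3 lectins and many interferon-stimulated genes were higher than in WT, and Paneth cell defensins and several transporters and enzymes of the villus brush border were lower. These are counts of single genes: camera called 25 of 47 lists at the preset correlation and 0 with an estimated correlation (1 at an unadjusted p under 0.05), where the 25 had adjusted p = 0.845 to 0.9 with an estimated correlation. Reg3b (XLOC_021649, chromosome 6, 78370884 to 78373466) and Reg3g, secreted antibacterial lectins, rose by 4.29 (SE 0.517) and 4.22 (SE 0.512) on the log2 scale (9 CF and 9 WT libraries). Slc34a2 (XLOC_019807, chromosome 5, 53043160 to 53071663), the brush border phosphate transporter, fell from 28.1 ± 23 to 0.694 ± 0.505 FPKM (SD, log2 change -3.92, SE 0.26, adjusted p = 1.55e-09). Of 12391 genes tested with limma, 2116 (17.1%) changed, 998 higher and 1118 lower in CF, and 220 changed at least 2-fold, 115 higher and 105 lower.

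The largest rise in the duodenum was that of Cfhr2 (XLOC_001378, chromosome 1, 139810291 to 139858722), a complement factor H-related gene, from 0.762 ± 0.657 to 43.9 ± 10.5 FPKM (log2 4.72, SE 0.188, adjusted p = 3.39e-13). Reg2, Gml and Duoxa2, the maturation factor of the hydrogen peroxide-producing oxidase Duox2, followed with 4.28, 3.53 and 3.36. Of 30 measured members of the list of epithelial antimicrobial and stress genes, 15 rose, 3 fell and 12 did not pass, and adjusted over the list alone 17 rose and 6 fell. The goblet cell product Retnlb in that list rose by 3.28 (SE 0.273). Of 39 interferon response genes, 24 rose, 2 fell and 13 did not pass (26 and 3 adjusted over the list alone), with Stat2 at 0.68 (SE 0.114) and the oligoadenylate synthetase-like Oasl1 at 1.08 (SE 0.188). Plasma cell markers rose in 5 of 10 and fell in 0 (6 and 0 adjusted over the list alone), among them Tnfrsf17 by 0.60 and Mzb1 by 0.73. For Mzb1, 7 of 9 CF libraries lay above the WT mean, and a Wilcoxon rank-sum test did not call it (adjusted p = 0.0538). In the list of oxidative phosphorylation subunits 10 of 44 rose and 0 fell (16 and 0 adjusted over the list alone), with Cycs at 0.75 (SE 0.151) and Cox5b at 0.60 (SE 0.146). With median-of-ratios scaling 36 of these 44 rose, and 10 rose without WT library 7.

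Falls in the duodenum were led after Slc34a2 by Cubn, the receptor that takes up vitamin B12 bound to intrinsic factor, which fell from 17.8 ± 12.3 to 0.219 ± 0.0704 FPKM (log2 -3.71, SE 0.263). Also lower were Naaladl1 (-3.13), a brush border peptidase, Slc5a4b (-3.01), Slc5a12 (-2.88), a sodium-coupled lactate transporter, and the Paneth cell defensin Defa3 (-2.81). The Defa3 locus holds 10 other coding genes of the same cluster. Amino acid and peptide transport genes fell in 12 of 24 and rose in 0 (12 and 2 adjusted over the list alone), including the meprin subunit Mep1a at -1.72 (SE 0.184) and the basolateral amino acid exchanger Slc7a8 at -1.04 (SE 0.115). In the brush border list of 9 hydrolases, which holds disaccharidases and other enzymes, 5 fell and 1 rose, and the same numbers passed when adjusted over the list alone. Lactase (Lct) there fell from 378 ± 90.5 to 68.9 ± 27.8 FPKM (log2 -2.52, SE 0.233). Paneth cell markers fell in 8 of 21 and rose in 0 (9 and 0 adjusted over the list alone). Stem cell markers fell in 9 of 20 and rose in 1 (10 and 1). Lgr5 fell from 3.37 ± 0.495 to 1.37 ± 0.206 FPKM (log2 -0.88, SE 0.0826, adjusted p = 2.99e-07). Xenobiotic and glutathione metabolism genes fell in 15 of 36 and rose in 2 (16 and 5 adjusted over the list alone), with Cyp3a25 at -2.04 and the carboxylesterase Ces2a at -1.96.

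Among the glucose genes of the duodenum, the apical sodium-glucose cotransporter Slc5a1 (XLOC_019720, chromosome 5, 33056819 to 33162699) was at 723 ± 147 FPKM in CF and 668 ± 95.1 in WT (log2 0.10, SE 0.142, adjusted p = 0.674). The facilitative transporter Slc2a2 (XLOC_016352, chromosome 3, 28695955 to 28732639) was at 208 ± 43.7 in CF and 272 ± 57.2 in WT (log2 -0.38, SE 0.159, adjusted p = 0.107). Slc2a2 was past the threshold with quantile normalization, with array weights, with the replicate number as a block (adjusted p = 0.0373) and without WT library 7 (log2 -0.49, adjusted p = 0.0118 without that library). The adjusted p of the alternatives ranged from 0.00658 to 0.132. The basolateral transporter Slc2a1 rose by 0.44 (SE 0.117, adjusted p = 0.0135), and the cotransporter family members Slc5a4a and Slc5a11 changed by -2.69 and -1.14. In the list of glucose and fructose transporters 2 of 15 rose and 3 fell, also when adjusted over the list alone. In the glycolysis list 3 of 26 rose and 1 fell (8 and 2 adjusted over the list alone), against 2 and 1 without WT library 7 and 16 and 3 with median-of-ratios scaling. Pfkfb3, which makes an activator of phosphofructokinase, rose from 6.55 ± 2.08 to 19.7 ± 6.47 FPKM (log2 1.43, SE 0.182, adjusted p = 1.5e-05), and Pfkfb4 rose by 0.55. Hexokinase 2 (Hk2, log2 0.60, adjusted p = 0.0493) and the enolase Eno3 (-0.44, adjusted p = 0.0414) stood close to the threshold. The call of Hk2 was kept only when the library left out was CF 2, 8 or 9, and that of Eno3 only when it was CF 4, 5, 7 or 9 or WT 6, 8 or 9, with adjusted p up to 0.0896 (alternatives from 0.00782) and 0.0765 (from 0.00189).

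In 30 of the 36 named genes past the threshold in the duodenum every CF library lay beyond the WT mean, and in 18 the groups did not overlap. Most named genes were picked from these same libraries by size of change or adjusted p. Such counts, here and in the other comparisons, are therefore no separate evidence and do not describe all genes. The gene count depended on scaling: 4833 changed with median-of-ratios scaling, 2918 higher and 1915 lower, and 3910 with quantile normalization, 1983 higher and 1927 lower. Without CF library 9 it was 4116. WT library 7 had the highest WT values of Slc34a2, Cubn, Naaladl1 and Slc5a12, and without it 1946 genes changed.

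In the CF jejunum, most genes of fatty acid oxidation and fat absorption were lower, and most genes of cholesterol synthesis and many of glycolysis and the hypoxia response were higher. Camera called 22 of 46 lists, and with an estimated correlation it called 1, which is none of these (adjusted p = 0.108, 0.194, 0.0763, 0.194 and 0.193 with an estimated correlation, in the order named). The 22 ranged from 0.0201 to 0.717 (10 lists at an unadjusted p under 0.05). Of 34 fatty acid oxidation and PPAR alpha target genes 32 fell and 0 rose, and of 25 cholesterol biosynthesis genes 22 rose and 0 fell. Hk2 (XLOC_024304, chromosome 6, 82725026 to 82774454), which phosphorylates glucose, rose to 19.4 ± 6.53 FPKM (SD, n = 9) from a WT mean of 5.24 (n = 8; log2 1.65, SE 0.14, adjusted p = 2.74e-08). Slc2a1 (XLOC_019861, chromosome 4, 119108744 to 119137329) rose from 5.48 ± 0.66 to 16.4 ± 4.04 FPKM (log2 1.40, SE 0.126, adjusted p = 6.3e-08). Of 12630 genes tested 3993 (31.6%) changed, 1394 higher and 2599 lower, and 377 changed at least 2-fold, 136 higher and 241 lower.

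The largest rise in the jejunum was that of Pla2g4c (XLOC_024929, chromosome 7, 13322926 to 13360812), a cytosolic phospholipase A2, from 0.628 ± 0.183 to 211 ± 135 FPKM (log2 6.43, SE 0.557, adjusted p = 3.62e-08). Retnlb (XLOC_010926, chromosome 16, 48816855 to 48818892) rose from 0.097 ± 0.174 to 55.5 ± 33.5 FPKM (log2 5.42, SE 0.325). Duoxa2 and Duox2, whose loci overlap on opposite strands, rose by 5.22 (SE 0.318) and 4.25 (SE 0.288), and Sprr2a3 and AA467197 by 4.27 and 3.77. The list of epithelial antimicrobial and stress genes had 22 of 32 members higher, 4 lower and 6 not passing (23 and 5 adjusted over the list alone). It was the 1 list of the jejunum still called with an estimated correlation (adjusted p = 0.0201 with an estimated correlation). Its camera p at the preset correlation was, however, as small in 11 of 100 random splits of the libraries, the real one included. Goblet cell and mucus genes rose in 11 of 21 and fell in 2 (11 and 3 adjusted over the list alone). Mast cell markers rose in 4 of 9 and fell in 0 (4 and 1 adjusted over the list alone). Cell division genes rose in 13 of 40 and fell in 0, also when adjusted over the list alone, and 27 rose with median-of-ratios scaling. Ribosomal protein genes rose in 11 of 42 and fell in 0, also when adjusted over the list alone, by small amounts such as 0.28 (SE 0.0688) for Rpl27 and 0.27 (SE 0.0682) for Rps12.

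Lower in the CF jejunum were Cubn (XLOC_016474, chromosome 2, 13276336 to 13493689), from 83.1 ± 27.9 to 0.862 ± 0.852 FPKM (log2 -5.51, SE 0.221, adjusted p = 1.77e-12). It was followed by the cytochromes P450 Cyp3a11 (-4.80, SE 0.273) and Cyp2b10 (-4.05, SE 0.296), the brush border phospholipase Plb1 (-3.58, SE 0.404), Slc5a12 (-3.40, SE 0.341) and Pdk4 (-3.20, SE 0.166), a kinase that inhibits pyruvate dehydrogenase. In the fatty acid oxidation list, where 32 fell and 0 rose also when adjusted over the list alone, the peroxisomal thiolase Acaa1b was at -3.08 (SE 0.192). Fat absorption and chylomicron assembly genes fell in 27 of 36 and rose in 1 (29 and 1 adjusted over the list alone), with the apolipoprotein Apoc3 at -2.56 (SE 0.173) and the fatty acid transporter Slc27a2 at -2.23 (SE 0.117). Xenobiotic metabolism genes fell in 22 of 36 and rose in 5 (23 and 5), with Cyp2d26 at -2.43 and Cyp3a25 at -2.90. Retinoid and vitamin genes fell in 17 of 23 and rose in 1 (17 and 1), with the retinaldehyde dehydrogenase Aldh1a1 at -2.31. Enterocyte markers fell in 22 of 32 and rose in 3 (25 and 3 adjusted over the list alone), and brush border hydrolases fell in 8 of 9 and rose in 0, also when adjusted over the list alone. Paneth cell markers fell in 14 of 21 and rose in 1 (14 and 2), and enteroendocrine genes fell in 13 of 17 and rose in 0 (14 and 0). T cell and innate lymphoid genes fell in 14 of 22 and rose in 0 (18 and 0 adjusted over the list alone). Macrophage and dendritic cell genes fell in 11 of 18 and rose in 1 (11 and 2), and MHC class II genes fell in 8 of 11 and rose in 0 (8 and 0).

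Cholesterol synthesis in the CF jejunum was represented by squalene epoxidase (Sqle), which rose by 1.91 (SE 0.117), and mevalonate kinase (Mvk), by 1.29 (SE 0.0879). In that list 23 genes rose and 0 fell when adjusted over the list alone. Glycolysis genes rose in 15 of 26, fell in 2 and did not pass in 9 (16 and 2 adjusted over the list alone). Among them were the aldolase Aldoa at 0.91 (SE 0.0819), lactate dehydrogenase Ldha at 0.65 (SE 0.0806) and the lactate exporter Slc16a3 at 1.31 (SE 0.122). Hypoxia targets rose in 11 of 22 and fell in 1, also when adjusted over the list alone, with the prolyl hydroxylase Egln3 at 1.89 (SE 0.159) and the carbonic anhydrase Car9 at 1.18 (SE 0.0934). Of 16 glucose and fructose transporters 3 rose and 7 fell (3 and 8 adjusted over the list alone). Slc2a2 (XLOC_017767, chromosome 3, 28695712 to 28732612) fell from 127 ± 29.5 to 62.3 ± 12.8 FPKM (SE of the log2 change 0.145, adjusted p = 2.34e-05). Slc5a4b, Slc5a4a and Slc5a11 changed by -2.74, -2.19 and -2.13. Slc5a1 was at 416 ± 85.1 FPKM in CF and 493 ± 51.1 in WT (log2 -0.27, SE 0.114, adjusted p = 0.086), and passed the threshold without CF library 2 or 3 (adjusted p down to 0.0422) and with quantile normalization (0.0238, the alternatives ranging from 0.0238 to 0.206).

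All 34 named genes past the threshold in the jejunum had every CF library beyond the WT mean, and in 31 the groups did not overlap. The share of changed genes that were higher was 34.9% as deposited and 53.8% with median-of-ratios scaling (2573 higher, 2207 lower) and 51.6% with quantile normalization (2388 higher, 2243 lower). Without CF library 7, 2095 were higher and 2582 lower, while the groups described kept their direction under both scalings.

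The ileum of CF mice, from 5 CF and 4 WT libraries, had many absorptive and digestive genes lower, and many glycolysis and hypoxia genes and markers of smooth muscle and fibroblasts higher. These too are counts of single genes: camera called 28 of 47 lists and 0 with an estimated correlation (12 at an unadjusted p under 0.05), where the 28 had adjusted p = 0.083 to 0.642 with an estimated correlation. Enterocyte markers fell in 25 of 31 and rose in 1, and brush border hydrolases fell in 9 of 9. Glycolysis genes rose in 16 of 26, fell in 1 and did not pass in 9. Slc2a2 (XLOC_015805, chromosome 3, 28697869 to 28730794) fell from 8.2 ± 4.28 (n = 4) to 0.116 ± 0.0749 FPKM (SD, n = 5; log2 -2.92, SE 0.255, adjusted p = 1.89e-05). Slc5a1 (XLOC_019113, chromosome 5, 33104104 to 33172372) fell from 360 ± 35.3 to 206 ± 17 FPKM (log2 -0.80, SE 0.085, adjusted p = 7.05e-05). Of 12947 genes tested 2935 (22.7%) changed, 1418 higher and 1517 lower, and 369 changed at least 2-fold, 147 higher and 222 lower.

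Retnlb (XLOC_009709, chromosome 16, 48816855 to 48818892) had the largest rise of the ileum when all libraries were kept, from 4.96 ± 4.01 to 658 ± 211 FPKM (log2 6.99, SE 0.412, adjusted p = 1.6e-06). Pla2g4c rose from 43.5 ± 78.5 to 1434 ± 370 FPKM (log2 6.85, SE 0.892, adjusted p = 0.000289), with WT library 2 at 161 FPKM and the other WT libraries between 3.04 and 4.82. Without that library the log2 change of Pla2g4c was 8.09, above that of Retnlb. The calpain Capn13 rose by 3.86, and the gasdermins Gsdmc2 and Gsdmc4, which share a locus with Gsdmc and Gsdmc3, by 3.69 and 3.63. U90926 was at 26.2 ± 8.44 FPKM in CF and 1.54 ± 1.75 in WT. Goblet cell and mucus genes rose in 13 of 22 and fell in 2 (14 and 3 adjusted over the list alone). Smooth muscle markers rose in 13 of 22 and fell in 0 (15 and 0 adjusted over the list alone). Fibroblast and matrix genes rose in 14 of 27 and fell in 0 (16 and 0 adjusted over the list alone), with fibronectin (Fn1) up from 23.5 ± 0.323 to 71.6 ± 9.99 FPKM and the collagen Col5a1 at 0.62 (SE 0.0632).

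Enpp7 (XLOC_003971, chromosome 11, 118988186 to 118993376), the alkaline sphingomyelinase of the brush border, fell from 62.7 ± 23.7 to 0.854 ± 0.734 FPKM in the ileum (log2 -5.12, SE 0.311, adjusted p = 1.88e-06). Cubn fell from 147 ± 33.3 to 7.03 ± 3.8 FPKM. Plb1 was at -4.23 (SE 0.285), the brush border scaffold Pdzk1 at -4.04 (SE 0.105), Cyp3a25 at -4.01 (SE 0.144) and the amino acid transporter Slc7a15 at -3.99 (SE 0.376). Adjusted over the list alone, enterocyte markers fell in 27 and rose in 1, and brush border hydrolases fell in 9 and rose in 0, with trehalase (Treh) at -2.50 (SE 0.118). Amino acid and peptide transport genes fell in 19 of 25 and rose in 1, also when adjusted over the list alone, with the peptidases Mme at -3.50 and Cndp2 at -1.34. Fat absorption genes fell in 23 of 35 and rose in 2 (25 and 3 adjusted over the list alone), including the cholesterol importer Npc1l1 (-1.22) and the sterol exporter Abcg5 (-1.02). Fatty acid oxidation genes fell in 15 of 32 and rose in 1 (19 and 2), with Hadh at -0.85 and Cyp4f14 at -0.93. Retinoid and vitamin genes fell in 13 of 21 and rose in 2, also when adjusted over the list alone, with the riboflavin transporter Slc52a3 at -1.30 and the retinol dehydrogenase Rdh7 at -2.67. Xenobiotic metabolism genes fell in 17 of 31 and rose in 1 (17 and 2), with Cyp2d26 at -3.17. MHC class II genes fell in 7 of 11 and rose in 0 (8 and 0).

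Glycolysis genes of the ileum rose in 17 and fell in 1 when adjusted over the list alone, and the phosphofructokinase Pfkl (log2 1.04, SE 0.0682), hexokinase Hk1 (1.01, SE 0.0722), enolase Eno1 (0.91, SE 0.0664) and Slc16a3 (2.23, SE 0.163) were among them. Hk2 was at 37.2 ± 4.5 FPKM in CF and 25.9 ± 11.6 in WT (adjusted p = 0.116). Hypoxia targets rose in 17 of 23 and fell in 1 (18 and 1 adjusted over the list alone), with Pgk1 at 0.99 and Ddit4 at 1.07. Of 16 glucose and fructose transporters 3 rose and 6 fell (4 and 6 adjusted over the list alone), Slc5a4a by -2.09 and Slc5a11 by -3.34, while Slc2a1 was at 52.1 ± 23 FPKM in CF and 9.51 ± 0.938 in WT.

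All 35 named genes past the threshold in the ileum showed the change in every CF library, and in 35 the groups did not overlap. A Wilcoxon rank-sum test, with a smallest possible p of 0.0159 for 5 against 4, called 0 genes after adjustment and 3650 at an unadjusted p under 0.05. With that lower limit the rank test says little about single genes, and the calls come from limma alone.

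Crypts isolated from the jejunum are the part of the epithelium that holds stem, dividing and Paneth cells. CF crypts had most Paneth cell markers and fatty acid oxidation genes lower, and most cholesterol synthesis and some interferon response genes higher. Camera called 20 of 42 lists and 0 with an estimated correlation (6 at an unadjusted p under 0.05), where the 20 had adjusted p = 0.207 to 0.761 with an estimated correlation. Paneth cell markers fell in 15 of 21 and rose in 0 (16 and 1 adjusted over the list alone), fatty acid oxidation genes fell in 27 of 33 and rose in 0 (30 and 0). Cholesterol synthesis genes rose in 20 of 25 and fell in 0 (23 and 0). Angiotensinogen (Agt, XLOC_029053, chromosome 8, 124556586 to 124618731) fell from 13.3 ± 2.6 (n = 8) to 0.927 ± 0.274 FPKM (SD, n = 9; log2 -2.89, SE 0.113, adjusted p = 1.17e-12). Of 11044 genes tested 1620 (14.7%) changed, 629 higher and 991 lower, and 314 changed at least 2-fold, 96 higher and 218 lower.

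Retnlb again had the largest rise in CF crypts, from 0.423 ± 0.682 to 83.9 ± 45 FPKM (log2 5.81, SE 0.302, adjusted p = 1.09e-10), followed by Pla2g4c (4.82, SE 0.47), Sprr2a3 (4.72, SE 0.454), AA467197 (3.24, SE 0.345), Duoxa2 (3.21, SE 0.324) and the galactosyltransferase B3galt5 (2.92, SE 0.503). Epithelial antimicrobial and stress genes rose in 15 of 30 and fell in 3 (16 and 3 adjusted over the list alone), including the fucosyltransferase Fut2 by 2.79 (SE 0.247). Interferon response genes rose in 13 of 30 and fell in 0 (18 and 0 adjusted over the list alone), with Oas1g at 1.53 (SE 0.268). In the cholesterol list Mvd, an enzyme of the mevalonate pathway, rose by 1.02 (SE 0.121).

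Defa-rs7, a defensin-related gene whose locus also holds Defa23, fell by 4.75 (SE 1.5, adjusted p = 0.0378). Its call was kept only when the library left out was CF 1, 2 or 8 or WT 3, 5 or 7 (adjusted p up to 0.0827, the alternatives ranging from 0.0116). Other falls in CF crypts were those of Cubn (-3.07, SE 0.302), Cyp2b10 (-2.97, SE 0.327) and neuritin (Nrn1, -2.83, SE 0.137). In the Paneth cell list Gm14851 fell from 6454 ± 866 to 1265 ± 423 FPKM (log2 -2.40, SE 0.159) and the defensin Defa21 from 3299 ± 879 to 574 ± 261 (log2 -2.60, SE 0.234). The Gm14851 locus holds 9 other coding genes, among them defensins. Among lipid genes Angptl4, an inhibitor of lipoprotein lipase, changed by -2.36, the lipid droplet protein Plin2 by -0.96 and Slc27a2 by -1.04. Fat absorption genes fell in 14 of 36 and rose in 0 (23 and 0 adjusted over the list alone). Xenobiotic metabolism genes fell in 20 of 35 and rose in 2, also when adjusted over the list alone, with Cyp2c66 at -2.12 and Ces1d at -1.52. Retinoid and vitamin genes fell in 12 of 20 and rose in 0 (15 and 0), with Aldh1a1 at -2.80. Enterocyte markers fell in 14 of 32 and rose in 1 (21 and 2), the riser being adenosine deaminase (Ada, 1.90, SE 0.217). Amino acid transport genes fell in 10 of 24 and rose in 0 (16 and 1), with Mep1a at -2.08 and Slc16a10 at -0.95. Immediate early and heat shock genes fell in 13 of 26 and rose in 1 (15 and 1 adjusted over the list alone). The camera p of this list was as small in 16 of 100 random splits. Fosb, Hspa1b and Hspa1a were also higher in WT crypts than in WT whole jejunum. A part of the isolation in this fall, or in the difference from whole jejunum below, was not tested.

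Hk2 in CF crypts rose from 8.88 ± 1.49 to 19.6 ± 6.76 FPKM (log2 1.02, SE 0.146, adjusted p = 5.76e-05). Slc2a1 rose from 7.4 ± 0.926 to 14.2 ± 2.92 FPKM (log2 0.84, SE 0.107, adjusted p = 1.82e-05). Glycolysis genes rose in 7 of 26 and fell in 2 (11 and 2 adjusted over the list alone), with Pfkm, Aldoc and Hk1 at 0.52, 0.73 and 0.55. Hypoxia targets rose in 8 of 21 and fell in 1 (9 and 2). Of 14 glucose and fructose transporters 1 rose and 5 fell (1 and 6 adjusted over the list alone). Slc2a2 fell from 35.4 ± 18.5 to 11.9 ± 6.21 FPKM (log2 -1.47, SE 0.353, adjusted p = 0.00675), and Slc5a4b, Slc5a11 and Slc5a4a changed by -2.80, -2.41 and -1.87. Slc5a1 was at 122 ± 40.7 FPKM in CF and 192 ± 58.3 in WT (log2 -0.66, SE 0.226, adjusted p = 0.0539). It passed the threshold without CF library 2 or 7 or WT library 7 (log2 -0.72, adjusted p = 0.0428 without CF library 7) and under quantile normalization and array weights, with alternatives from 0.0147 to 0.0871.

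In 37 of the 38 named genes past the threshold in crypts every CF library lay beyond the WT mean, and in 25 the groups did not overlap. Without CF library 7, 1158 genes were higher and 1017 lower. With median-of-ratios scaling 1040 were higher and 1059 lower, and with quantile normalization 1232 and 1083, while the groups described kept their direction.

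**Figure D2:**
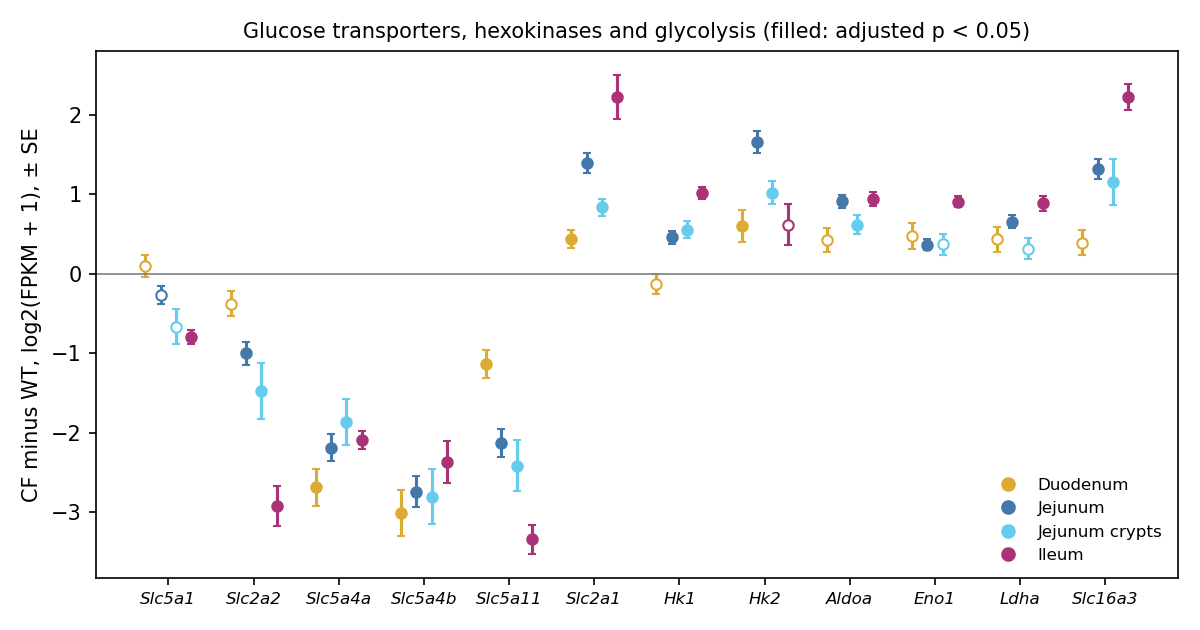
Log2 change of CF against WT (vertical axis, on log2(FPKM + 1)) of 12 genes of glucose transport and glycolysis (horizontal axis) in the duodenum, jejunum, ileum and jejunal crypts, with bars for the SE and filled points for an adjusted p under 0.05. Slc5a4a and Slc5a11 lie below 0 in all 4 comparisons and Slc2a1 above 0, from 0.44 in the duodenum to 2.23 in the ileum.

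**Figure D3:**
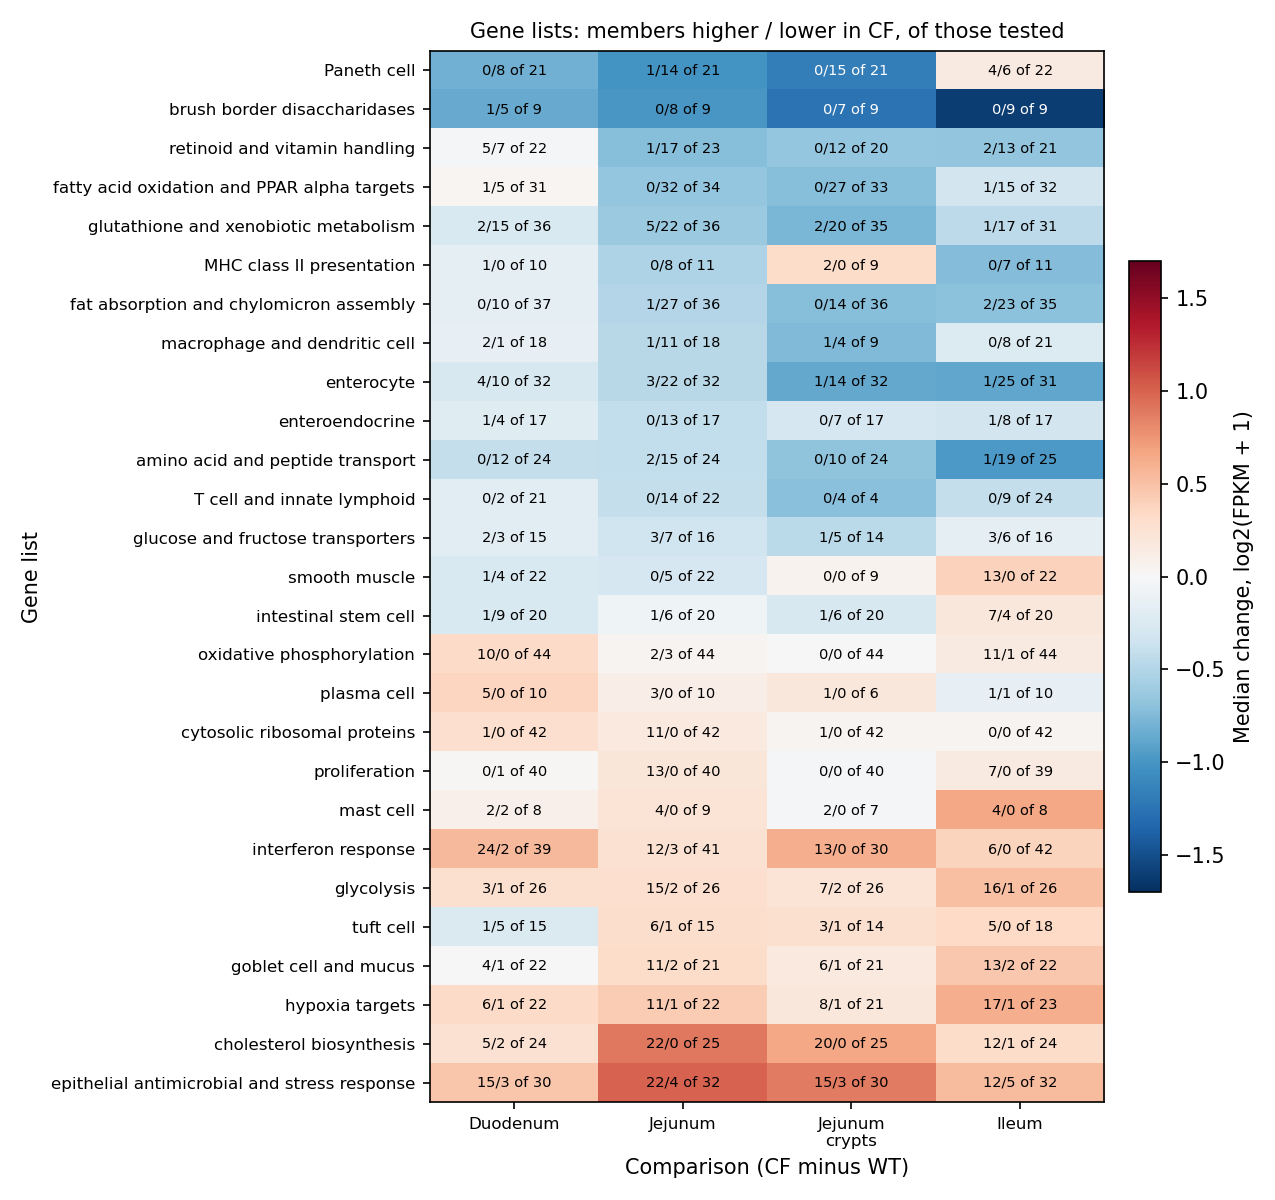
Median log2 change of CF against WT (colour) of gene lists (vertical axis) in the 4 comparisons (horizontal axis), with the numbers of members higher and lower of those tested printed in each cell. The 27 lists called by camera at the preset correlation in at least 2 of the 4 comparisons are drawn; with an estimated correlation camera called 0 lists in the duodenum, ileum and crypts and 1 in the jejunum. In the jejunum fatty acid oxidation genes fell in 32 of 34 and cholesterol synthesis genes rose in 22 of 25.

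Comparing the calls of the 3 whole-tissue segments asks which genotype differences run along the small intestine. Among 11451 genes tested in all 3, 169 were higher in CF in each and 262 were lower in each, where independent lists would share 11.4 and 23.4. Cubn had changes of -3.71 in the duodenum, -5.51 in the jejunum and -4.33 in the ileum, and Retnlb of 3.28, 5.42 and 6.99. Duoxa2 (3.36, 5.22 and 2.72) and Duox2 (2.79, 4.25 and 2.52), Gml2 (3.04, 2.72 and 2.19) and Fut2 (2.12, 3.58 and 3.17) rose in each. Slc5a4b (-3.01, -2.74 and -2.37), Slc5a4a (-2.69, -2.19 and -2.09), Cyp3a25 (-2.04, -2.90 and -4.01) and Ces2a (-1.96, -2.16 and -2.20) fell in each. The jejunum and ileum shared 628 genes that were higher in both and 932 lower in both, with 62 opposite, where independence would give 148, 293 and 432. The duodenum and ileum shared 222 and 302, with 125 opposite (expected 103, 115 and 217), and the duodenum and jejunum 376 and 577, with 67 opposite (expected 103, 211 and 306). The 3 segments may come from the same animals, which the labels do not state, so the expected numbers are no test. Without WT duodenum library 7 the genes shared by all 3 numbered 408, and with median-of-ratios scaling 764.

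Crypts of WT mice were compared with WT whole jejunum to see what the isolation enriched. Smooth muscle and stromal markers were far lower in crypts, most villus markers were lower, and dividing and Paneth cell markers were higher. Acta2 (XLOC_014912, chromosome 19, 34192226 to 34255511), the smooth muscle actin, fell from 108 ± 15 in whole tissue (SD, n = 8) to 0.389 ± 0.407 FPKM in crypts (n = 8; log2 -6.33, SE 0.145, adjusted p = 2.01e-28). The muscle genes Myl9 (-6.30) and Actg2 (-6.25), the plasma cell gene Jchain (-6.07) and the pericyte gene Rgs5 (-5.82) followed. Fibroblast genes fell in 24 of 24, smooth muscle genes in 22 of 22, endothelial genes in 17 of 17 and enterocyte genes in 31 of 32, and 0 rose in these lists. Cell division genes rose in 40 of 40, ribosomal protein genes in 42 of 42, Paneth cell genes in 20 of 21 and stem cell genes in 17 of 20, with 1 lower. All of these counts were the same when adjusted over the list alone. Defa-rs7 rose by 5.71 (SE 1.46, adjusted p = 0.000732), Defa5 by 2.58 (SE 0.545), the immediate early gene Fosb by 2.89 (SE 0.247) and the heat shock genes Hspa1b and Hspa1a by 2.62 (SE 0.506) and 2.46 (SE 0.425). The villus genes Slc5a1 and Slc2a2 were at -1.42 and -1.98, smaller falls than those of the muscle genes. Whether villus tissue left in the crypt libraries adds to their genotype differences was not tested. In all 9091 genes changed, 5059 higher and 4032 lower in crypts, and 2633 changed at least 2-fold, 1046 higher and 1587 lower. Camera called 24 of 46 lists and 2 with an estimated correlation, the fibroblast and endothelial lists (adjusted p = 0.042 each with an estimated correlation), and the 24 had adjusted p = 0.042 to 0.492 with an estimated correlation.

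The genotype effect in crypts was then compared with that in whole jejunum, by testing the crypt change minus the whole-tissue change. Some immediate early, heat shock and cholesterol genes had a lower difference, and some MHC class II genes a higher one. Camera called 20 of 46 lists for the difference and 0 with an estimated correlation (5 at an unadjusted p under 0.05), where the 20 had adjusted p = 0.173 to 0.83 with an estimated correlation. In the list of immediate early and heat shock genes 7 of 27 had a lower difference and 0 a higher one (11 and 0 adjusted over the list alone), in the cholesterol list 4 of 25 and 0 (13 and 0), and in the MHC class II list 0 of 9 had a lower and 3 a higher difference (0 and 7). The invariant chain Cd74 had a difference of 1.75 (SE 0.429, adjusted p = 0.0171), being at 75.1 ± 23.3 FPKM in CF and 44.2 ± 33.9 in WT crypts and at 191 ± 25.1 and 307 ± 69.1 in whole tissue. Mast cell genes had a lower difference in 4 of 9 and a higher one in 0, also when adjusted over the list alone. Of 12066 genes tested 306 differed, 202 with a higher and 104 with a lower difference, and 62 differed at least 2-fold.

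Agt fell by more in crypts than in whole jejunum (difference -1.32, SE 0.17, adjusted p = 6.42e-06), as did Nrn1 (-1.24, SE 0.161) and the Wnt inhibitor Sfrp5 (XLOC_014977, chromosome 19, 42197970 to 42202252; -1.40, SE 0.121, adjusted p = 1.27e-09). Ctsl, a lysosomal protease, had a difference of 0.97 (SE 0.13) and Hoxa3, a positional transcription factor, of 1.14 (SE 0.15), with crypt means of 1.57 ± 0.436 FPKM in CF and 0.139 ± 0.0646 in WT. Gml2 (-2.17) and Gml (-2.49) were listed at 0 in WT crypts. Mcoln3 (1.60), Cym (1.68) and Cxcl12 (0.85) had crypt means of at most 1.17 FPKM. Mcoln3 kept its call under every alternative that tested it. With a pseudocount of 0.1 the adjusted p of Cym was 0.336 and that of Cxcl12 0.67 (alternatives from 2.83e-08 and 4.57e-06). The difference was not past the threshold for Cftr (-0.35, adjusted p = 0.552), Slc2a2 (-0.47, adjusted p = 0.83), Slc5a1 (-0.40, adjusted p = 0.695), Hk2 (-0.63, adjusted p = 0.118) or Slc2a1 (-0.56, adjusted p = 0.0746).

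Between whole jejunum and crypts, 453 genes were higher in both and 792 lower in both of 10751 tested in both, with 8 opposite, where independence would give 73.9, 174 and 227. Both preparations came from the divided jejunum section and may share animals, so these expected numbers are no test. The test of the difference treats whole and crypt samples as independent, and the number of genes with a different effect depended on choices such as the filter, with 100 at a mean of at least 5 FPKM and 708 without a filter. It was also higher with the replicate number as a block.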

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

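The tests on WT duodenum library 7 and on the share of enterocytes were chosen only after those results were seen, as was the position measure itself, while the tests that weigh the position of the CF jejunum were set before their own values were computed. A single-library check of the named genes, with 294 tests, singled out 29 groups, and chance alone does so in about 1 in 20 groups.

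WT duodenum library 7 stood apart in Mep1a (0.584; 49.8 FPKM against 12.7 to 22.6), Naaladl1 (0.695; 254 against 15.6 to 37.3), Slc2a2 (0.692; 137 against 247 to 321), Slc34a2 (0.53; 87.3 against 15.6 to 35.4) and Slc5a12 (0.631; 39.4 against 3.92 to 9.7). On 128 genes that differ between WT duodenum (position 0) and WT jejunum (position 1) it lay at 0.787, where the other 8 WT libraries lay between -0.0574 and 0.0604. Exchanged genotype labels are argued against by a position of -0.306 between the WT and CF means, and scaling by a factor of 1.09, but its Cftr of 12 FPKM lay within the CF range (7.65 to 14.3) and below every other WT library of the duodenum and every WT library of the jejunum (23.9 to 33.9). Its position was 0.993 on genes higher in duodenum and 0.3 on genes higher in jejunum, and a jejunum library in its place would lie near 1 on both. A section taken further down the tract may explain the position of 0.787 but not the Cftr value, and the cause stays open.

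CF jejunum libraries lay between 0.143 and 0.324 (median 0.228) on genes that differ 4-fold between WT jejunum (0) and WT ileum (1), and WT libraries between -0.0502 and 0.0974; the ileum end of this scale comes from another table and instrument. CF sections from further down would also carry ileum genes, and on those the CF median was 0.0176, within the WT range (highest 0.0749). With median-of-ratios scaling that median was 0.0424, and the highest CF library (0.0866) lay above the highest WT library (0.0753). WT duodenum library 7 moved much less on genes of the other segment (0.3) than on those of its own (0.993). A small shift down the tract may thus leave little trace on ileum genes, and it is not excluded. After median-of-ratios scaling the lowest CF position was 0.135 and the highest WT position 0.0984, which argues against scaling. An effect of the genotype on jejunum genes could give the position of 0.296 on genes higher in jejunum, and stays open as a hypothesis.

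Enterocyte markers were lower in CF, and a smaller share of enterocytes alone would move Paneth and goblet cell markers alike. The goblet cell mean change minus the Paneth cell mean change was 1.02 (SE 0.263) in the duodenum, 1.51 (SE 0.146) in the jejunum, 0.57 (SE 0.158) in the ileum and 1.51 (SE 0.175) in crypts, which argues against that explanation. The goblet cell list holds Retnlb, with a log2 change of 6.99 in the ileum. Its mean therefore does not follow cell share alone, and the explanation is not excluded. Changes in several cell types could underlie differences such as 1.51, and stay open.

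In the duodenum single libraries also stood apart for Hk2 in WT (0.496; library 9 at 2.89 FPKM against 3.88 to 5.15), Lgr5 in CF (0.608; library 3 at 0.888 against 1.27 to 1.56), Pfkfb4 in CF (0.545; library 9 at 27.1 against 40.2 to 55.8) and WT (0.501; library 9 at 18.1 against 28.1 to 43.2), Slc5a1 in CF (0.571; library 9 at 405 against 650 to 928) and Slc5a4a in CF (0.54; library 5 at 5.6 against 0.416 to 1.87). Library 9 of either genotype is low in each of its 4 values, and its median-of-ratios factors were 0.666 in CF and 0.7 in WT, against 0.988 to 1.09 in the other duodenum libraries. In the jejunum single libraries stood apart for Cubn in CF (0.645; library 2 at 3.06 against 0.335 to 0.981), Cyp2d26 in WT (0.561; library 6 at 132 against 191 to 254), Retnlb in WT (0.597; library 6 at 0.497 against 0 to 0.177) and Slc5a4a in CF (0.503; library 1 at 1.63 against 3.03 to 5.15). In the ileum WT library 2 stood apart for Capn13 (0.855; 12.9 against 3.67 to 4.47), Gsdmc4 (0.877; 242 against 47.4 to 58) and Pla2g4c (0.901; 161 against 3.04 to 4.82). CF library 2 of the ileum did for Pgk1 (0.729; 371 against 276 to 299), Slc52a3 (0.842; 41.1 against 49.2 to 50.8) and U90926 (0.753; 12 against 25.9 to 33.2), and CF library 3 for Rdh7 (0.717; 0.413 against 0.171 to 0.235). Crypt libraries stood apart for Cubn (0.675; CF 2 at 0.629 against 0.00357 to 0.175), Cyp2b10 (0.571; CF 2 at 2.13 against 0.245 to 0.85), Cyp2c66 (0.6; CF 8 at 0.416 against 1.73 to 3.24), Mvd (0.524; CF 3 at 14.7 against 21.2 to 29.3) and Slc27a2 (0.686; WT 7 at 29.8 against 50.3 to 63.9).

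The genotype effect differed between crypts and whole jejunum for Mcoln3 (1.60), Cym (1.68), Cxcl12 (0.85), Hoxa3 (1.14), Ctsl (0.97), Sfrp5 (-1.40), Gml2 (-2.17), Gml (-2.49), Agt (-1.32) and Nrn1 (-1.24).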

How the results depend on the processing

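The run without libraries of low scale (median-of-ratios factor under 0.8) and the overlap without WT duodenum library 7 were chosen only after the result was seen. Duodenum genes numbered 2116, and 1289 at a mean of at least 5 FPKM, 4833 with median-of-ratios scaling, 3910 with quantile normalization, 5972 with array weights, 5399 with the replicate number as a block and 5034 without libraries of low scale. Leaving out 1 library gave from 1646 (without CF library 6) to 4116 (without CF library 9). The log2 change of Slc5a1 in the duodenum was -0.11 with quantile normalization (adjusted p = 0.497, alternatives from 0.15 to 0.88) and 0.10 as deposited, and neither passed. Crypt genes numbered 1620, and 1070 at a mean of at least 5 FPKM and 3200 with array weights. Genes with different genotype effects in crypts and whole jejunum numbered 306, and 180 with a pseudocount of 0.1, 708 without a filter, 100 at a mean of at least 5 FPKM, 588 with quantile normalization, 574 with array weights and 735 with the block. Whole and crypt libraries of the same number correlated by a mean of 0.25 in CF (other pairs -0.031) and 0.12 in WT (other pairs -0.016), with 5 of 9 and 3 of 8 closest to their own number, a hint from the data and not the design. The labels do not pair CF with WT libraries. Genes changed the same way in all 3 segments numbered 431, and 764 with median-of-ratios scaling, 737 with quantile normalization, 828 with array weights and 408 without WT duodenum library 7. In the ileum the Wilcoxon rank-sum test called 0 of 12947 genes (3650 at an unadjusted p under 0.05, smallest adjusted p 0.0739). With an estimated correlation camera called 0 lists in the duodenum (1 at an unadjusted p under 0.05), 1 in the jejunum, 0 in the ileum (12), 0 in crypts (6), 0 for the difference of genotype effects (5) and 2 for crypts against whole jejunum. The cause of these differences in counts was not tested.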

Other observations

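The position measure, the window around Cftr, the genes read in single libraries and the count of splits for each list by itself were chosen only after the result was seen, while the splits themselves were set beforehand.

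Bile acid genes of the CF ileum fell in 7 of 11 and rose in 1 (8 and 1 adjusted over the list alone). The bile acid binding protein Fabp6 was at 2490 ± 290 FPKM in CF (SD, n = 5) and 9765 ± 1006 in WT (n = 4), a log2 change of -1.97, and the hormone Fgf15 at 25.7 ± 17.3 and 79.5 ± 30.8. Mast cell markers of the CF ileum rose in 4 of 8 and fell in 0, also when adjusted over the list alone. Mcpt1, a mast cell protease, was at 46.6 ± 27.8 FPKM in the CF jejunum (n = 9) and 2.18 ± 0.73 in WT (n = 8). Enteroendocrine genes fell in 8 of 17 in the ileum and rose in 1, also when adjusted over the list alone, and in 7 of 17 in crypts (8 adjusted over the list alone), with 0 higher. Gip, an incretin hormone, was at -1.07 in the jejunum and -1.31 in the ileum.

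In the duodenum iron and heme genes rose in 4 of 13 and fell in 0, also when adjusted over the list alone. The iron exporter Slc40a1 was at 328 ± 82.9 FPKM in CF and 112 ± 61 in WT (n = 9 each), and Pdx1, a transcription factor of the proximal intestine, ranged from 23 to 53 in CF and from 4.54 to 21.8 in the 8 WT libraries other than library 7. WT library 7, which is part of the Slc40a1 mean, was at 5 FPKM for Slc40a1 and at 0.0188 for Pdx1. Tuft cell markers fell in 5 of 15 and rose in 1 in the duodenum (6 and 1 adjusted over the list alone), and in the jejunum 6 of 15 rose and 1 fell (7 and 1).

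Random splits of the samples, 100 with the real one, give the number of splits with at least as many calls. For genes chance is excluded in the duodenum (1; 2116 real, highest other 0), jejunum (1; 3993, 857), ileum (1; 2935, 1410) and crypts (1; 1620, 15), and for genes changed at least 2-fold in the duodenum (1; 220, 0), jejunum (1; 377, 158), ileum (1; 369, 248) and crypts (1; 314, 9). The count shared by all 3 segments (1; 431, 0) adds no separate test, because other splits of the duodenum called 0 genes. As many lists as in the real split were called in fewer than 5 of 100 splits in the duodenum (4; 25, 27) and ileum (3; 28, 30). Random splits there called a median of 14 and 15 lists, and the highest called more than the real one. By this count chance is thus not excluded for the number of lists or for single lists. A called list had a p as small in fewer than 5 of 100 splits for 2 of 25 lists in the duodenum, 7 of 22 in the jejunum, 13 of 28 in the ileum and 3 of 20 in crypts, and for 0 lists when set against the smallest p of any list. The p was as small in 33 splits for the interferon list and 23 for the Paneth cell list of the duodenum. For smooth muscle in the ileum it was as small in 20. In the jejunum only 1 split, the real one, gave such a p for cholesterol synthesis, fatty acid oxidation, fat absorption and hypoxia targets, against 7 for glycolysis. Chance is also not excluded for the number of lists in the jejunum (31; 22, 29), crypts (31; 20, 28), the difference of genotype effects (47; 20, 29) and crypts against whole jejunum (60; 24, 33). The genes that differ between WT crypts and whole jejunum (1; 9091, 7900) exclude it. For the genes that differ in genotype effect (2; 306, 633) the splits shuffled genotypes within each tissue. A shuffle that follows the real genotypes more in 1 tissue than in the other turns the common genotype effect into a difference. These splits therefore cannot exclude chance for the difference by itself. One split gave 633 calls, about 2 times the real number, and whether the genotype effect or other structure among the samples gave them was not tested.

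Between WT duodenum (0) and WT jejunum (1), CF duodenum libraries lay from -0.117 to 0.00804 (median -0.066) and the 8 WT libraries other than library 7 from -0.0574 to 0.0604 (median 0.00572). On genes higher in duodenum the CF libraries lay from -0.235 to 0.0343 (median -0.17), and these WT libraries from -0.164 to 0.191 (median -0.0111). On genes higher in jejunum the medians were 0.00227 in CF and 0.0144 in WT. Whether CF duodenum sections lay further up the tract, and whether this adds to the changes in the duodenum, was not tested. Between WT ileum (0) and WT jejunum (1), CF ileum libraries lay from -0.0627 to -0.0303 and WT libraries from -0.0278 to 0.0434.

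Genes within 5 Mb of Cftr passed in 4 of 17 in the duodenum (23.5%, against 17.1% elsewhere), 3 of 16 in the jejunum, 2 of 17 in the ileum and 0 of 13 in crypts (Fisher's exact p = 0.515, 0.42, 0.391 and 0.238). Prss2, a pancreatic protease, ranged from 12.7 to 925 FPKM in the CF duodenum and from 0 to 825 in the WT duodenum, where Cela1 and Cpa1 varied with it. CF jejunum library 8 listed Prss2 at 42.1 FPKM, and the other jejunum libraries listed it at 0.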
